A study of Mus musculus with 8 samples.

How the data were processed

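Gene expression was measured in CD4 T cells sorted from the colonic lamina propria of mice, on Affymetrix Mouse Genome 430 2.0 arrays. The 8 arrays formed 8 groups of 1 array. The 4 C57BL/6 arrays held wild-type and Uhrf1 knockout cells, each sorted into Foxp3-positive regulatory T cells (Treg) and Foxp3-negative cells (Non-Treg). The 4 arrays of the IQI strain held cells from specific-pathogen-free (SPF) and germ-free mice, sorted by the surface markers FR4 and CD25. Strain and sort markers therefore changed together. Per the labels' protocols, RNA was extracted with TRIZOL LS or a RNeasy micro kit and amplified with the Ovation system. Which kit served which array is not given in the sources used here. For the IQI arrays the title and the cell subtype label name opposite subtypes, and groups were taken from the titles. Nothing in the labels says whether an array held cells of 1 mouse or a pool, or that arrays came from separate animals. The p-values therefore measure only part of the spread between these arrays, and that part may be technical.

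The deposited values were MAS5 signal intensity on a linear scale, per the submitters' processing notes, which give no version and no scaling target. Each deposited column had a median of 1, so a signal of 1 is the median probe set of its array. No detection calls were used here. Absolute brightness before this scaling is not known, and the number of arrays limits the precision. The 75th percentile of the deposited signals ran from 5.72 in germ-free Treg to 9.98 in wild-type Treg. Of 45101 probe sets, 34958 named 1 gene in the platform annotation, 932 named several and 9211 named none. Entrez identifiers of 34754 matched the mouse gene table of assembly GRCm38.p6, which was used for names only, and 0 symbols changed. No genome build or coordinates entered the work.

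Signals were transformed as log2(signal + 0.239), with the 25th percentile of all deposited values as the pseudocount, so a log2 change understates the change of dim genes. Each of 18194 genes was represented by its probe set with the highest mean, and 10443 genes with a mean log2 value above 0.29, the 50th percentile of all probe sets, were tested. Among them 6574 had several probe sets. For named genes with several probe sets above the filter, 8 of 112 gene and contrast pairs held a probe set of opposite sign, for Dnmt1, Cdkn1b, Pdk1 and Xiap in the knockout contrast and for Dnmt1, Slbp, Usp7 and Pim1 in the germ-free contrast.

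Contrasts were fitted with limma 3.58.1 in R 4.3.3, with condition and cell subtype as additive terms over all 8 arrays and variances moderated with a trend on mean expression. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The 3 residual degrees of freedom measured how far the 4 conditions departed from a common Treg minus Non-Treg difference. Real differences between conditions in that quantity count as error. A shift shared by both arrays of a condition, for example between mice, never enters this error. In the knockout and germ-free contrasts such a shift counts fully as effect. Moderation added a prior of 59.5 degrees of freedom, and the significance of most genes rests on that prior. Interaction terms, tested 1 at a time with 2 residual degrees of freedom, asked whether the knockout effect, the germ-free effect or the Treg effect differed between groups; their prior was infinite. Within a subtype each condition had 1 array, so genes with a 2-fold or larger ratio were counted without a test, and a gene list's median was placed among 10000 random lists matched on mean expression.

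The 26 gene lists, with 413 genes, of which 32 had no probe set naming them alone, covered Treg signature, effector Treg, conventional CD4 T cell, G2 and M phase, S phase, CDK inhibitor, p53 target, DNA methylation, germline, imprinted, Th1, Th2, Th17, IL-2 response, glycolysis, immediate early and heat shock, interferon response, homing receptor, exhaustion and apoptosis, and T cell identity genes. Marker lists for B cells, myeloid, epithelial, stromal and endothelial, CD8 T and NK, and red blood cells covered cells that a sort could carry over. The red blood cell list had 0 genes above the filter. The further lists of B cell, Reg family, matrix, stromal and pancreatic enzyme genes used for weighing explanations were added after the main results were seen. The other fixed lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 75 list and contrast pairs. Of these, 34 passed and 0 passed with an estimated correlation. That setting also lowers the degrees of freedom of the test to the 3 residual ones, so lost calls are largely built in. Lists with an estimated correlation under the preset lost their calls too, as did conventional CD4 genes at -0.038 in the Treg contrast. The loss therefore does not show that correlation undid a call. Beside each list stands the number of members that passed when adjusted over the list alone.

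The groups, contrasts, gene lists, filter, pseudocount and the first set of other settings were fixed before the data were examined. Named genes were the 10 largest rises and 10 largest falls per contrast among genes that passed with the same sign in every pair of arrays, the 4 members of each list with the largest changes, the 5 largest per direction within a subtype and per interaction, and a fixed set of further genes, not all of which are reported here. Alternatives were other pseudocounts, quantile normalization, other filters, the mean of a gene's probe sets, no variance trend, other model terms, single strains and the removal of each array; beside a call that removing an array ended, the adjusted p given is the highest over the 8 removals. In the Treg contrast, leaving out either array of a condition gives the same estimate, from the other conditions alone. Such removals are a single check, and only the moderated variance, and so p, differs between them. Added after seeing the data were scaling to a 2% trimmed mean or to the 75th percentile, a pseudocount of 5, each gene's own variance, and the Treg contrast within each strain.

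Some choices were corrected after results had been seen. A first coding of the interactions compared 1 condition with the mean of the other 3, which is not the difference named; it called 62, 282 and 136 genes for the knockout, germ-free and strain terms, against 5, 138 and 136 in the coding used. A synonym lookup that had placed wrong genes in the glycolysis and imprinted lists was fixed, as was a partial name match that had blocked the alternative pseudocounts. The test of array scaling for the interferon genes was limited to quantile normalization, because a factor per array hardly moves a list's median relative to that of all genes. The verdict on genes silent in 1 genotype was made stricter for counts under 10, and that on B cell genes as a property of colonic Treg cells was made to require both IQI conditions.

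The fits were tested on simulated data with 5 sets of 200 changed genes among 10443. The noise was drawn for each array separately, with no shift shared by both arrays of a condition. With noise drawn from each gene's own residual spread, 88% of log2 changes of 2 were recovered for Treg against Non-Treg, 58.8% for knockout against wild type and 53.6% for germ-free against SPF. With noise from the moderated spread these shares were 100%, 92.4% and 94.8%. For the knockout and germ-free interactions, log2 changes of 4 were recovered in 0% and 0% with the first kind of noise and in 89.2% and 90.8% with the second. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.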

Results

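The study profiled regulatory and conventional CD4 T cells of the mouse colon and asked, as far as its title states, how they differ in germ-free mice and in mice lacking Uhrf1, which recruits the maintenance DNA methyltransferase to hemimethylated DNA. There was 1 array for each of wild-type, Uhrf1 knockout, SPF and germ-free mice in each subtype. Foxp3, the lineage transcription factor of Treg cells, had signals of 38.6 to 71.2 in the 4 arrays titled Treg and of 1.15 to 2.88 in the 4 titled Non-Treg. Arrays of one strain correlated at 0.888 or more. Across genes, which are not independent replicates, log2 values correlated at r = 0.979 between wild-type and knockout Non-Treg and at 0.962 between wild-type and knockout Treg, against 0.738 to 0.852 between arrays of different strains. The ratio of 3′ to 5′ Gapdh probe sets, a sign of RNA integrity, was 1.28 to 1.36 in C57BL/6 arrays, 1.52 in SPF Treg, 1.69 in SPF Non-Treg, 2.0 in germ-free Treg and 1.69 in germ-free Non-Treg. The Actb ratio was 1.36 to 1.41 in C57BL/6 arrays, 1.86 in SPF Treg, 2.10 in SPF Non-Treg, 2.89 in germ-free Treg and 2.35 in germ-free Non-Treg.

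Markers of other cells differed between the strains. The median signal of epithelial markers was 0.331 to 0.388 in C57BL/6 arrays and 6.30 to 11.2 in IQI arrays. Stromal and endothelial markers had medians of 0.364 to 1.0 in C57BL/6 arrays, 12.6 in SPF Treg, 17.1 in SPF Non-Treg, 4.08 in germ-free Treg and 2.31 in germ-free Non-Treg. B cell and plasma cell markers had medians of 18.4 in wild-type Treg and 53.4 in knockout Treg, against 1.37 and 1.15 in the matching Non-Treg arrays. In IQI mice their medians were 2.29 in SPF Treg, 1.61 in SPF Non-Treg, 9.12 in germ-free Treg and 3.54 in germ-free Non-Treg. T cell identity genes had medians of 76.9 to 159 in all 8 arrays. Red blood cell markers stayed at medians of 0.07 to 0.607 and were not tested.

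**Figure D1:**
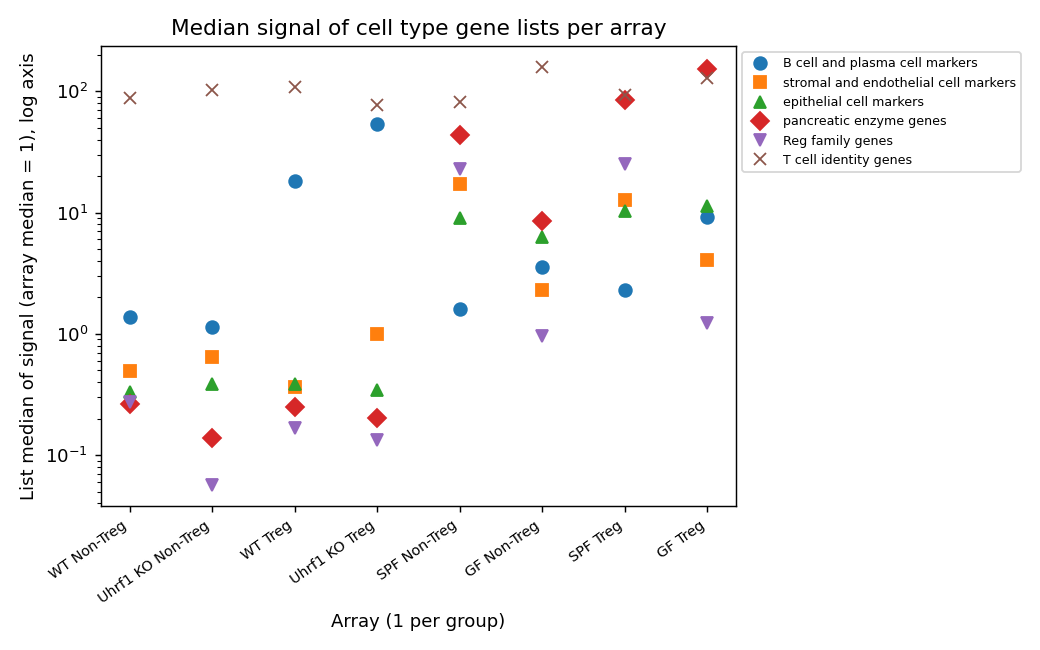
Median deposited signal (array median 1, log axis) of the B cell, stromal, epithelial, pancreatic enzyme, Reg family and T cell identity genes in each of the 8 arrays, 1 point per array. B cell markers reach 53.4 in knockout Treg and 18.4 in wild-type Treg, and Reg family genes drop from 25.1 and 23.0 in SPF arrays to 1.22 and 0.96 in germ-free arrays.

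The first comparison set Treg against Non-Treg cells over the 4 conditions. Treg cells carried the sort marker and other regulatory genes at higher levels. Foxp3 was higher by 4.84 ± 0.28 (log2, SE; limma adjusted p = 9.82e-22), with a mean signal of 55.1 ± 16.4 (SD, n = 4 arrays) against 1.74 ± 0.81. Next came Klrg1, a receptor of terminally differentiated lymphocytes, at 4.36 ± 0.32 (limma adjusted p = 5.91e-17), and Il2ra, the high-affinity IL-2 receptor chain, at 4.30 ± 0.30. Ebi3, Itgae, Gzmb and Fgl2 were higher by 4.14, 4.03, 3.84 and 3.65, and Itgb8 and Gpr15, an integrin chain and a colon homing receptor, by 3.60 and 3.58. Il10, an anti-inflammatory cytokine, was higher by 3.61 ± 0.38, but its Treg minus Non-Treg difference ran from 0.19 in the knockout to 6.05. The largest falls in Treg cells were Pdlim4 at -3.72 ± 0.28 (limma adjusted p = 1.94e-16), Ggt5 at -3.40, Vwce at -2.75 and Dntt, the terminal deoxynucleotidyl transferase, at -2.73. Lypd6b, Ampd1, Hs3st3b1, Tdrp, Il1rl2 and Arhgap29 fell by 2.68 to 2.11.

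**Figure D2:**
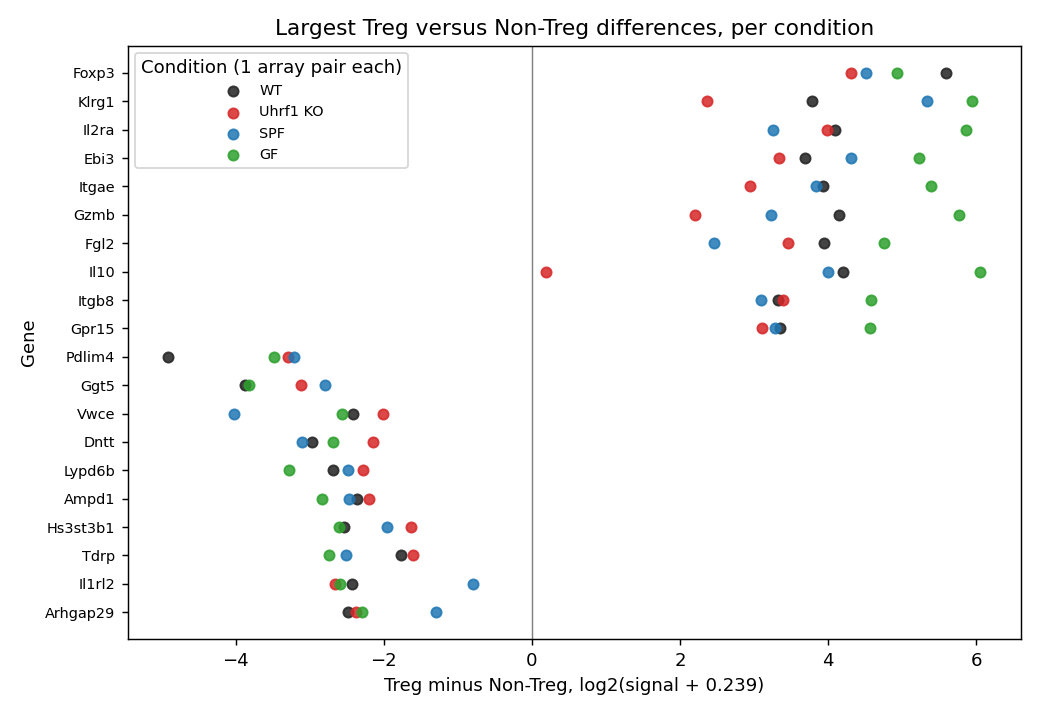
Treg minus Non-Treg difference (log2) of the 10 genes with the largest rise and the 10 with the largest fall, with 1 point per condition (wild type, Uhrf1 knockout, SPF, germ-free). Foxp3 lies between 4.31 and 5.60 in all 4 conditions, while Il10 lies at 0.19 in the knockout.

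Of 10443 genes, 911 passed in this comparison, 702 higher and 209 lower in Treg, and 773 had the same sign in each of the 4 pairs. All 22 measured Treg signature genes rose, as did all 22 adjusted over the list alone (camera adjusted p = 1.58e-65, and adjusted p = 0.131 with an estimated correlation). Besides those above, Socs2, Plagl1, Il2rb and Ctla4 rose by 3.37, 2.65, 2.30 and 2.11, and Izumo1r, which encodes the FR4 used for sorting in IQI mice, rose by 1.15. Since Foxp3, FR4 and CD25 defined the sorts, their differences are not findings. Among 15 effector Treg genes 13 rose, 0 fell and 2 did not pass, and 13 rose adjusted over the list alone (camera adjusted p = 1.24e-28, and adjusted p = 0.222 with an estimated correlation). Gata3, a regulator of tissue Treg and Th2 cells, rose by 1.17 (limma adjusted p = 0.00183), a call lost without SPF Treg (adjusted p = 0.085) and without SPF Non-Treg. Of 15 conventional CD4 T cell genes 7 fell and 1, Rora, rose, the same numbers adjusted over the list alone (camera adjusted p = 2.36e-05, and adjusted p = 0.194 with an estimated correlation); Pde3b, Igfbp4 and Themis fell by 1.48, 1.38 and 1.29. Rora rose by 1.13, a call lost without knockout Treg (adjusted p = 0.0621), where the estimate was still 1.13. In this contrast, leaving out either array of a condition gives the same estimate, so the removals of a pair are a single check. The count of 911 went to 585 without knockout Treg and to 601 without knockout Non-Treg, and to 2 with each gene's own variance.

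The medians of the proliferation lists were higher in Treg than in Non-Treg cells in 3 of the 4 conditions, each from 1 pair of arrays. A difference between conditions in these medians was not tested. The median Treg minus Non-Treg difference of the G2 and M phase list was 1.08 in wild type, 1.41 in the knockout, 0.52 in SPF and -0.17 in germ-free mice, and that of the S phase list was 0.46, 0.60, 0.51 and -0.59. B cell markers, in the same order, had medians of 2.65, 4.69, 0.32 and 0.99. Mki67, a marker of cycling cells, rose by 1.70 ± 0.27 (limma adjusted p = 2.41e-06), with 1.49 to 1.86 in the 4 conditions. Of 25 G2 and M phase genes 11 rose and 14 did not pass, with 13 rising adjusted over the list alone (camera adjusted p = 1.58e-08, and adjusted p = 0.494 with an estimated correlation). Melk and Bub1, both mitotic kinases, rose by 1.83 and 1.30; Bub1 was lost without knockout Treg (adjusted p = 0.072) or wild-type Treg, and Melk after trimmed mean scaling. In the S phase list 3 of 27 rose and 4 adjusted over the list alone (camera adjusted p = 0.0115, and adjusted p = 0.848 with an estimated correlation), a call ended by removing either knockout or either SPF array (adjusted p = 0.317 without knockout Treg). Tk1 rose by 1.68. Among 5 CDK inhibitors Cdkn1a alone rose, by 1.27 (limma adjusted p = 0.000485), while 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.564, and adjusted p = 0.891 with an estimated correlation). Uhrf1 differed by 0.80 ± 0.28 (limma adjusted p = 0.0583) and Dnmt1 by -0.19 (limma adjusted p = 0.797), neither past the threshold. Of 16 DNA methylation genes Tet1, a demethylating dioxygenase, fell by 1.78 and 0 rose, with 1 rise and 1 fall adjusted over the list alone (camera adjusted p = 0.621, and adjusted p = 0.931 with an estimated correlation).

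Some cytokine response, homing and helper T cell genes rose in Treg cells, and most members of the IL-2 response, homing, Th17 and Th1 lists did not pass or fell. In the knockout the medians of the homing and Th1 lists were -0.14 and -0.03. Of 14 IL-2 response genes 6 rose, also adjusted over the list alone (camera adjusted p = 1.46e-08, and adjusted p = 0.194 with an estimated correlation), with Nfil3 at 2.12. Of 14 homing receptors 6 rose and S1pr1 fell, with 6 rises and 2 falls adjusted over the list alone (camera adjusted p = 7.61e-05, and adjusted p = 0.267 with an estimated correlation); Ccr2 and Ccr9 rose by 3.05 and 1.75. Of 10 Th17 genes 3 rose, also adjusted over the list alone (camera adjusted p = 0.00125, and adjusted p = 0.494 with an estimated correlation), among them Ccr6 at 2.12 and Ahr at 1.91. Of 10 Th1 genes 4 rose, also adjusted over the list alone (camera adjusted p = 0.000321, and adjusted p = 0.494 with an estimated correlation), with Il18rap at 1.86 and Cxcr3 at 1.44. Both lists lost their calls without germ-free Treg or germ-free Non-Treg (adjusted p = 0.395 for Th17 and 0.146 for Th1 without the latter). Of 5 Th2 genes 3 rose and 4 adjusted over the list alone (camera adjusted p = 8.47e-05, and adjusted p = 0.439 with an estimated correlation). Ifng at 0.16 and Il17a at -0.42 did not pass (limma adjusted p = 0.893 and 0.658).

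B cell genes moved with the Treg sort. Of 11 measured B cell and plasma cell markers 10 rose, also adjusted over the list alone (camera adjusted p = 1.01e-17, and adjusted p = 0.267 with an estimated correlation). Cd79b, a chain of the B cell receptor, rose by 3.19 and Cd79a by 2.48, whereas Ebf1 ranged from -0.29 to 5.86 over the 4 conditions and was lost under 3 other scalings. The list's median difference was 2.65 in wild type, 4.69 in the knockout, 0.32 in SPF and 0.99 in germ-free mice. Of 9 myeloid markers 2 rose and 4 adjusted over the list alone (camera adjusted p = 0.00125, and adjusted p = 0.467 with an estimated correlation), a call lost without knockout Treg (adjusted p = 0.206) or knockout Non-Treg. Of 7 CD8 T and NK markers 2 rose and 1 fell, with 3 rises and 2 falls adjusted over the list alone (camera adjusted p = 0.215, and adjusted p = 0.494 with an estimated correlation); Gzma and Cd8a rose by 2.57 and 1.59.

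Of the remaining lists the imprinted genes alone had a camera call in the deposited scaling. Imprinted genes had 1 rise among 7, Plagl1, also adjusted over the list alone (camera adjusted p = 0.0442, and adjusted p = 0.417 with an estimated correlation), a call ended by removing either knockout or either germ-free array (adjusted p = 0.221 without germ-free Non-Treg) and by each other scaling. Of 15 interferon genes 1 rose and 2 adjusted over the list alone (camera adjusted p = 0.764), and of 15 epithelial markers 2 rose, also adjusted over the list alone (camera adjusted p = 0.197). Of 18 p53 targets 3 rose, also adjusted over the list alone (camera adjusted p = 0.251). Of 14 glycolysis genes 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.107), with Hk2 at 1.53. Of 14 exhaustion and apoptosis genes Bcl2l1 alone rose, by 1.42, also adjusted over the list alone (camera adjusted p = 0.308). Of 4 germline genes 1 fell, with 1 rise and 1 fall adjusted over the list alone (camera adjusted p = 0.793). None of 10 stromal, 10 T cell identity and 18 immediate early genes passed, with 1 rise and 1 fall adjusted over the list alone in the stromal list (camera adjusted p = 0.550, 0.765 and 0.793). Leaving out 1 array brought the CD8 T and NK list past the threshold without either wild-type array (adjusted p = 0.023 and 0.021) and the glycolysis list without either germ-free array (adjusted p = 0.0462 and 0.0425). The glycolysis list also passed after quantile normalization, trimmed mean and 75th percentile scaling (adjusted p = 0.0065, 0.0192 and 0.0257).

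The second comparison set Uhrf1 knockout against wild-type cells of both subtypes. Uhrf1 itself had signals of 16.8 in wild-type and 12.2 in knockout Non-Treg, 32.2 in wild-type and 24.7 in knockout Treg, 16.4 in SPF Non-Treg, 37.7 in SPF Treg, 10.05 in germ-free Non-Treg and 10.6 in germ-free Treg. The knockout difference was -0.41 ± 0.39 (limma adjusted p = 1.0) and did not pass. A probe set outside the deleted part of a gene checks nothing, and whether this one lies in it is not given in the sources used here. The response was led by interferon-induced genes. Slfn4, a Schlafen family member induced by interferon, rose by 5.02 ± 0.40 (limma adjusted p = 1.39e-14), from signals of 0.92 and 0.95 in wild type to 26.7 and 53.8. The antiviral effectors Rsad2, Mx1, Oas2, Ifitm3, Ifit3 and Oasl2 rose by 3.94, 3.90, 3.69, 3.34, 3.33 and 3.26, in both subtypes. Clvs1 and Mnd1, the latter a meiotic recombination factor, rose by 4.20 (limma adjusted p = 5.22e-09) and 3.69 (limma adjusted p = 2.35e-08), with the Clvs1 call lost after quantile and trimmed mean scaling. Cep112 rose by 3.64, a call lost under 3 other scalings and without knockout Treg (adjusted p = 0.14).

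**Figure D3:**
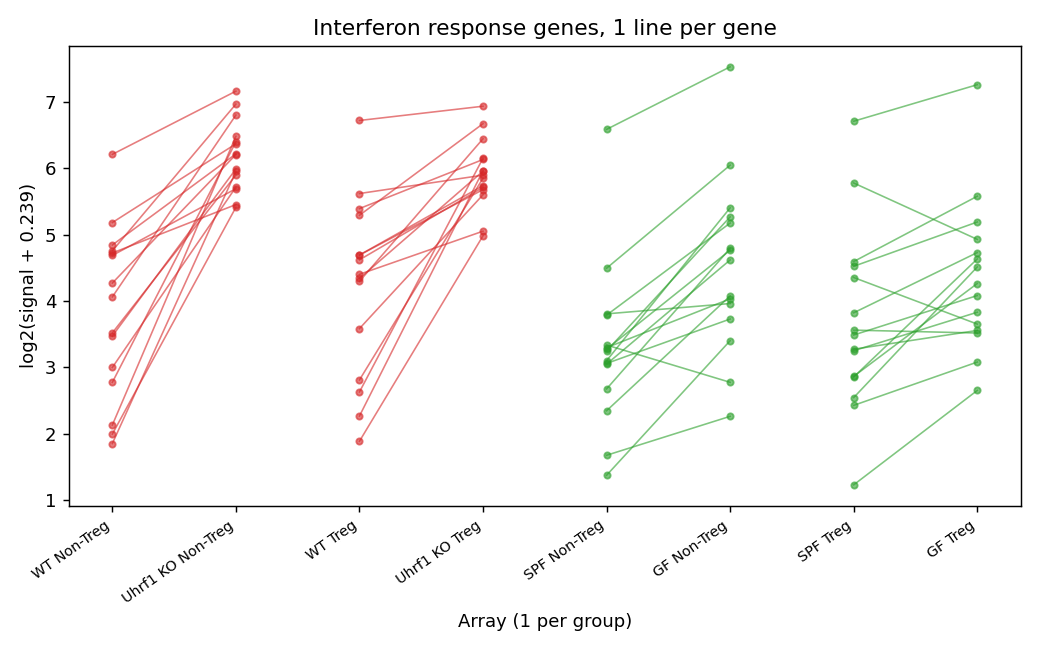
Deposited signals, as log2(signal + 0.239), of the 15 measured interferon response genes, 1 line per gene, joining wild type to Uhrf1 knockout and SPF to germ-free within each subtype (1 array per point). All 15 lines go up from wild type to knockout in both subtypes.

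Of 10443 genes 77 passed, 73 higher and 4 lower in the knockout. Of 15 interferon genes 10 rose, 0 fell and 5 did not pass, with 14 rising adjusted over the list alone (camera adjusted p = 2.08e-79, and adjusted p = 0.131 with an estimated correlation). The list's median ratio was 1.38 within Treg and 2.38 within Non-Treg. The genes lower in the knockout were Cxcl13, a B cell chemokine, at -2.49 (limma adjusted p = 0.000145), Sccpdh at -2.21, Vdr at -1.59 and Ttc28 at -1.52. All 4 were lost under 3 other scalings, with 21 genes higher and 0 lower under every scaling, and all 4 were lost when single arrays were left out (adjusted p = 1.0 without knockout Non-Treg for Cxcl13 and without wild-type Treg for the others). Cxcl13 was also lost without wild-type Non-Treg, the others without knockout Treg, Vdr and Ttc28 without wild-type Non-Treg and Ttc28 without knockout Non-Treg. Gbp2b, at -1.71, did not pass (limma adjusted p = 0.0744). The count went to 35 without knockout Treg, 48 without wild-type Treg and 139 without knockout Non-Treg, and to 0 with each gene's own variance, where limma left 292 genes at an unadjusted p under 0.05.

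Of the Th1 and the CD8 T and NK lists, 2 genes each rose in the knockout. Ifng, the signature Th1 cytokine, had signals of 3.24 in wild-type and 16.8 in knockout Non-Treg and of 2.99 and 7.71 in Treg, a rise of 1.79 (limma adjusted p = 0.0105), and Ccl5 rose by 1.57 (limma adjusted p = 0.0222). Of 10 Th1 genes 2 rose, with 6 adjusted over the list alone (camera adjusted p = 5.04e-16, and adjusted p = 0.267 with an estimated correlation), and the list's median ratio was 0.80 within Treg and 1.44 within Non-Treg. Ccl3 at 1.77 and Nkg7 at 1.46 did not pass (limma adjusted p = 0.0925 and 0.0589). Of 7 CD8 T and NK markers 2 rose, with 5 adjusted over the list alone (camera adjusted p = 2.14e-14, and adjusted p = 0.131 with an estimated correlation); Gzma rose by 2.25 and Klrd1 by 1.94, with -0.18 within Non-Treg and 4.06 within Treg for the latter. The median ratio of the CD8 T and NK list was 1.86 within Treg and 0.15 within Non-Treg. In the same order, B cell markers had medians of 1.49 and 0.05, myeloid markers of 1.49 and 0.29, and stromal markers of 1.15 and 0.38. The calls of Ifng and Klrd1 were lost under 3 other scalings and that of Gzma after trimmed mean scaling. Leaving out 1 array ended the call of Ifng (adjusted p = 1.0 without knockout Non-Treg, and lost without either wild-type array), of Ccl5 (0.857 without knockout Non-Treg, and lost without any other C57BL/6 array), of Gzma (0.149 without knockout Non-Treg) and of Klrd1 (1.0 without wild-type Treg, and lost without knockout Treg or either germ-free array).

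B cell, myeloid, stromal and epithelial marker lists also gave camera calls in the knockout, with Col1a1 as the 1 single gene past the threshold. In C57BL/6 arrays the median signal was 0.331 to 0.388 for epithelial and 0.364 to 1.0 for stromal markers, so their ratios rest mostly on dim genes. Myeloid markers had medians of 0.843 in wild-type and 1.20 in knockout Non-Treg, and of 1.29 and 4.91 in Treg. B cell markers had 0 rises among 11 and 1 adjusted over the list alone (camera adjusted p = 6.16e-06, and adjusted p = 0.494 with an estimated correlation), with median ratios of 1.49 within Treg and 0.05 within Non-Treg, and the direction reversed without knockout Treg (median -0.85). Myeloid markers had 0 rises among 9 and 1 adjusted over the list alone (camera adjusted p = 1.35e-09, and adjusted p = 0.263 with an estimated correlation), a call lost without knockout Treg (adjusted p = 0.445). Of 10 stromal markers Col1a1 rose, by 2.32, with 6 rising adjusted over the list alone (camera adjusted p = 1.28e-12, and adjusted p = 0.194 with an estimated correlation), and Col1a1 was lost without knockout Treg (adjusted p = 0.927) and under 3 other scalings. Epithelial markers had 0 rises among 15, also adjusted over the list alone (camera adjusted p = 0.0387, and adjusted p = 0.591 with an estimated correlation), a call lost without wild-type Treg, knockout Non-Treg (adjusted p = 0.463) or either SPF array and under 3 other scalings.

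Cell cycle and Treg genes gave no single call. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, differed by 1.07 ± 0.39 (limma adjusted p = 0.458), with 1.02 and 1.12 in the subtypes. Mki67 differed by 0.30 and Foxp3 by -0.15, neither past the threshold. The Foxp3 value is the mean of opposite ratios. Within Treg it was at -0.79, with signals of 67.1 in wild type and 38.6 in the knockout. Within Non-Treg it was at 0.50, from low signals of 1.15 and 1.72. G2 and M phase genes had 0 rises among 25, also adjusted over the list alone, with a median of 0.37 (camera adjusted p = 6.30e-07, and adjusted p = 0.494 with an estimated correlation), a call lost without knockout Treg (adjusted p = 0.942). The Treg signature had 0 of 22 past the threshold, also adjusted over the list alone, with a median of -0.26 (camera adjusted p = 0.0188, and adjusted p = 0.631 with an estimated correlation), a call lost without knockout Treg (adjusted p = 0.981) or wild-type Non-Treg. Effector Treg genes had 0 of 15 and 1 rise adjusted over the list alone, with a median of -0.43 (camera adjusted p = 0.0381, and adjusted p = 0.757 with an estimated correlation); that call ended without wild-type Non-Treg (adjusted p = 0.718) or either germ-free array, and without knockout Treg the direction reversed (median 0.037). Both Treg lists were lost after trimmed mean scaling. Il10 differed by -2.81 within Treg and 1.21 within Non-Treg, the latter from signals of 0.24 and 0.87, both under the array median. Of 4 germline genes Rpl39l rose, by 2.34, and 2 rose adjusted over the list alone (camera adjusted p = 6.24e-06, and adjusted p = 0.229 with an estimated correlation), though Rpl39l was lost without wild-type Treg (adjusted p = 0.63) and under 3 other scalings.

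No further list passed in the knockout. CDK inhibitors, Th17 and immediate early genes had 1 rise each adjusted over the list alone (camera adjusted p = 0.132, 0.136 and 0.0934), the last being Ier3 at 1.95, which was lost without wild-type Treg (adjusted p = 1.0) or knockout Non-Treg and under 3 other scalings. No member of the S phase, p53, DNA methylation, imprinted or Th2 lists passed, also adjusted over the list alone (camera adjusted p = 0.260, 0.467, 0.550, 0.875 and 0.550). The same held for conventional CD4, IL-2 response, glycolysis, homing, exhaustion and T cell identity genes (camera adjusted p = 0.362, 0.765, 0.793, 0.793, 0.793 and 0.875). The median and the tested direction differed in sign for the p53, imprinted, glycolysis, immediate early, IL-2 response and T cell identity lists, and the median and mean for homing receptors. Leaving out 1 array gave calls for CDK inhibitors (median 0.43, adjusted p = 0.0268) and S phase genes (0.30, adjusted p = 0.0041) without knockout Non-Treg, and for homing (0.26, adjusted p = 0.0165), T cell identity (0.20, adjusted p = 0.0342) and Th17 genes (0.32, adjusted p = 0.00309) without knockout Treg. Th17 genes also passed without wild-type Non-Treg (0.19, adjusted p = 0.000182) and Th2 genes without wild-type Treg (-0.62, adjusted p = 0.000283).

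Within subtypes, without replicates and therefore without a test, 351 genes were at least 2-fold higher and 202 lower in knockout Treg, and 192 higher and 66 lower in knockout Non-Treg. The median of all genes was -0.23 in the former and 0.06 in the latter, and the Treg split became 415 and 103 after quantile normalization, 453 and 97 after trimmed mean scaling and 445 and 92 after 75th percentile scaling. Beside the interferon genes, Klrd1 was higher by 4.06 in knockout Treg, where Gbp2b, Sccpdh and Il10 were at -3.31, -3.06 and -2.81. In knockout Non-Treg, Cxcl13 was at -4.00 and Bmpr1a, a BMP receptor, at -2.12. The knockout ratios of the subtypes correlated across genes at r = 0.35 (Spearman's rho 0.20), while 47.6% of genes had the same sign in both, and genes are not independent replicates.

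The third comparison set germ-free against SPF IQI mice. Among the named genes, Reg2 and Reg3b fell most steeply. They belong to the Reg genes, which encode secreted antimicrobial and regenerative lectins of the gut epithelium and pancreas. Reg2 fell by 6.62 ± 0.45 (log2, SE; limma adjusted p = 4.80e-18), from signals of 118 and 69.7 to 0.98 and 0.47, and Reg3b and Reg3g fell by 5.84 and 4.22. Il1r1, the IL-1 receptor, fell by 4.91 (limma adjusted p = 2.14e-12), Htra1 by 3.97, Nebl by 3.89, Ccn2 by 3.73 and Tnfaip6 by 3.67. Xist, the transcript that silences an X chromosome, fell by 5.37 ± 0.38 (limma adjusted p = 1.22e-17), while the Y-linked Eif2s3y, named after its values were seen, had signals of 69.8 and 79.2 in SPF and 144 and 149 in germ-free arrays. The sex of the mice is not given in the sources used here. Bright Eif2s3y with Xist near the array median is the pattern of male cells, and both bright together that of mixed sexes. By these transcripts the sex makeup differed between germ-free and SPF arrays, so the fall of Xist is not a finding about microbes. Sex was not separated from the germ-free condition in any value of this comparison. Among the largest rises were Calr3 at 3.43 (limma adjusted p = 7.35e-07), lost under quantile and trimmed mean scaling, and the interferon genes Mx1 at 1.85 ± 0.39 (limma adjusted p = 0.000428) and Oas2 at 1.78. Other large rises, Igkv15-103, Ryr2, St8sia6, Cd79a, Fcrla, Ttll9 and Ighv14-2 at 3.17 to 1.82, were lost under quantile and trimmed mean scaling, all but St8sia6 and Ttll9 also under 75th percentile scaling, and each without at least 1 array (germ-free Non-Treg for Igkv15-103, with an adjusted p of 0.947, SPF Non-Treg for Ttll9, at 0.397, and SPF Treg for the others, at 0.191 to 0.978). Germ-free Non-Treg also ended the calls of Ryr2, Cd79a, Fcrla and Ighv14-2, and germ-free Treg that of Fcrla.

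**Figure D4:**
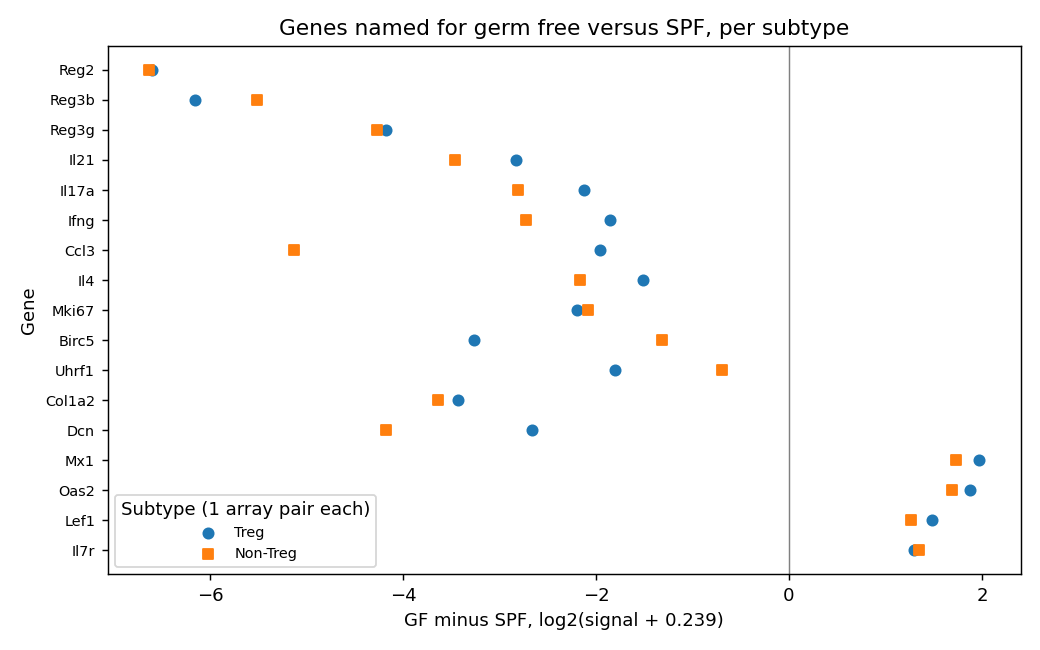
Germ-free minus SPF difference (log2) within Treg and within Non-Treg for 17 genes, 1 point per subtype, each from 1 pair of arrays. Reg2 lies at -6.60 and -6.63, Mki67 at -2.20 and -2.08, and Mx1 at 1.97 and 1.73, in Treg and Non-Treg.

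Of 10443 genes 807 passed, 399 higher and 408 lower in germ-free mice, and the balance depended on the scaling. The share of higher genes was 49.4% in the deposited scaling, 9.17% of 109 after quantile normalization, 25.7% of 272 after trimmed mean scaling and 71.8% of 949 after 75th percentile scaling. The median change of all genes was 0.07, -0.00, -0.11 and 0.12 in that order, and 7 genes were higher and 91 lower under every scaling. The 7 were Ifit3, Mx1, Oas2, Oasl2, Rnf213, Rtp4 and Usp18, of which Rnf213 and Rtp4 were named after their values were seen. The count went to 356 without SPF Non-Treg, 416 without SPF Treg and 1649 without germ-free Treg, and to 0 with each gene's own variance, where limma left 1243 genes at an unadjusted p under 0.05.

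Most members of the Th17 and Th1 lists were lower in germ-free mice, as were most stromal and some myeloid markers. Of 10 Th17 genes 7 fell, also adjusted over the list alone (camera adjusted p = 2.36e-13, and adjusted p = 0.229 with an estimated correlation), and of 10 Th1 genes 8 fell, also adjusted over the list alone (camera adjusted p = 6.28e-11, and adjusted p = 0.337 with an estimated correlation). Among these genes Il1r1 is also known from stromal cells, and Tmem176a, Tmem176b, Ccl3 and Ccl4 from myeloid cells. In the same arrays 8 of 10 stromal markers fell, with a list median of -2.62, and 4 of 9 myeloid markers, with a list median of -1.17. The Actb ratio of 3′ to 5′ probe sets was higher in both germ-free arrays (2.89 and 2.35) than in both SPF arrays (1.86 and 2.10). These values stand beside the proliferation, Treg and interferon lists of this comparison too. Il21, a cytokine of helper T cells, fell by 3.15 ± 0.45 (limma adjusted p = 5.05e-07), and Nkg7, a cytotoxic granule protein, by 2.12. Ifng fell by 2.30 (limma adjusted p = 4.63e-05), which quantile normalization and trimmed mean scaling moved to an adjusted p of 0.105 and 0.0516. Il17a, the signature Th17 cytokine, fell by 2.47 (limma adjusted p = 0.000188), lost under the 3 other scalings (0.0986, 0.0776 and 0.0549) and without germ-free Non-Treg (0.114). Of 5 Th2 genes 1 fell, Il4, by 1.84, and 2 adjusted over the list alone (camera adjusted p = 0.0549, and adjusted p = 0.628 with an estimated correlation); the Il4 call was lost without germ-free Non-Treg (adjusted p = 0.197) or SPF Treg and under 3 other scalings.

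Some proliferation genes fell as well. Of 25 G2 and M phase genes 9 fell, 11 adjusted over the list alone (camera adjusted p = 1.58e-08, and adjusted p = 0.494 with an estimated correlation). Mki67 fell by 2.14 ± 0.38 (limma adjusted p = 4.17e-05), Birc5, an inhibitor of apoptosis active in mitosis, by 2.30 and Bub1 by 2.25, and the calls held under each scaling and array removal. Of 27 S phase genes Tk1 fell and Pcna rose, also adjusted over the list alone (camera adjusted p = 0.228), both lost after quantile normalization, without SPF Treg and without germ-free Treg for Tk1 (adjusted p = 0.0612) or SPF Non-Treg for Pcna (0.281), the latter also without germ-free Non-Treg. Uhrf1 fell by 1.25 ± 0.39 (limma adjusted p = 0.0325), by 1.81 in Treg and 0.69 in Non-Treg. The Uhrf1 call was lost after quantile normalization (adjusted p = 0.0546) and without any array but germ-free Non-Treg (adjusted p = 0.535 without SPF Treg). In the DNA methylation list it was the 1 gene of 16 that fell, also adjusted over the list alone (camera adjusted p = 0.550; median 0.03, mean -0.12, tested direction downward).

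Among Treg genes, 5 of 22 signature genes fell, 6 adjusted over the list alone (camera adjusted p = 1.99e-05, and adjusted p = 0.467 with an estimated correlation), and 4 of 15 effector genes, 5 adjusted over the list alone (camera adjusted p = 0.000176, and adjusted p = 0.494 with an estimated correlation). Both lists lost their calls, and their direction relative to the other genes reversed, without germ-free Non-Treg (adjusted p = 0.855 and 0.829); the signature was also lost without SPF Non-Treg. Il2ra, Entpd1 and Gzmb fell by 2.05, 2.02 and 2.18, with Il2ra and Gzmb lost under the 3 other scalings, Entpd1 under quantile and trimmed mean scaling, and each without at least 1 array (adjusted p = 0.203 and 0.281 without SPF Non-Treg for Il2ra and Entpd1, both also lost without germ-free Non-Treg, and 0.206 without germ-free Non-Treg for Gzmb). Foxp3 at -0.92 and Il10 at -1.56 did not pass (limma adjusted p = 0.181 and 0.0645). Of 15 conventional CD4 genes Lef1, Satb1 and Il7r rose, by 1.37, 1.36 and 1.32, with 4 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.0095, and adjusted p = 0.267 with an estimated correlation). These 3 genes were lost after quantile normalization, Satb1 also after trimmed mean scaling, and the list was lost without germ-free Treg (adjusted p = 0.201) and after quantile or 75th percentile scaling. Of 10 T cell identity genes 4 rose and 5 adjusted over the list alone (camera adjusted p = 0.000417, and adjusted p = 0.494 with an estimated correlation), a call that quantile normalization ended. Cd3e rose by 1.11, turned to -0.045 there and was lost without SPF Non-Treg (adjusted p = 0.0746).

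Of 15 interferon genes 7 rose in germ-free mice and 0 fell, 10 adjusted over the list alone (camera adjusted p = 6.53e-07, and adjusted p = 0.467 with an estimated correlation). Ifit3, Oasl2 and Usp18 rose by 1.76, 1.73 and 1.64, although each lost its call without 1 array (adjusted p = 0.126 and 0.0823 without SPF Non-Treg for Ifit3 and Oasl2, and 0.129 without SPF Treg for Usp18).

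Stromal genes were lower in germ-free arrays. Of 10 stromal and endothelial markers 8 fell, also adjusted over the list alone (camera adjusted p = 2.99e-19, and adjusted p = 0.180 with an estimated correlation). The matrix genes Col1a2, Bgn, Dcn and Col3a1 fell by 3.54, 3.43, 3.42 and 3.11. Of 9 myeloid markers 4 fell, 5 adjusted over the list alone (camera adjusted p = 7.61e-05, and adjusted p = 0.417 with an estimated correlation), a call lost without SPF Non-Treg (adjusted p = 0.135). Of 15 epithelial markers 0 passed, also adjusted over the list alone (camera adjusted p = 0.162), with Muc2 at -1.17. Of 11 B cell markers Cd79a and Ms4a1 rose, also adjusted over the list alone (camera adjusted p = 0.228); both were lost without SPF Treg or germ-free Non-Treg and under 3 other scalings, and Ms4a1, also lost without germ-free Treg, turned to -0.13 without SPF Treg. The B cell list itself passed downward without SPF Treg (median -0.47, adjusted p = 0.00206) and upward without SPF Non-Treg (median 1.69, adjusted p = 1.15e-11). Of 7 CD8 T and NK markers 1 fell and 2 adjusted over the list alone (camera adjusted p = 0.550), with a median of 0.33 against a tested direction downward.

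Homing receptors split in germ-free mice. Of 14 genes 4 rose and 4 fell, with 5 and 5 adjusted over the list alone (camera adjusted p = 0.550). Ccr2, Gpr15, Cxcr6 and Ccr9 fell by 2.48, 2.28, 1.94 and 1.85, while Ccr7, Cxcr4, S1pr1 and Klf2, named after their values were seen, rose. None of these rises was among the 7 genes higher under every scaling. Of the falls, quantile normalization ended the calls of Ccr2, Gpr15 and Cxcr6, trimmed mean scaling also those of Ccr2 and Cxcr6, and 75th percentile scaling that of Cxcr6, and leaving out 1 array ended those of Cxcr6 (adjusted p = 0.354 without germ-free Non-Treg, and lost without SPF Treg) and Ccr9 (adjusted p = 0.27 without SPF Treg). The other lists had no camera call in the deposited scaling: immediate early genes with 5 rises and 3 falls among 18 and 6 and 3 adjusted over the list alone (camera adjusted p = 0.0636), IL-2 response genes with 1 rise and 2 falls among 14, also adjusted over the list alone (camera adjusted p = 0.0739, and 0.0223 after quantile normalization, which passed), and imprinted genes with 2 falls among 7, also adjusted over the list alone (camera adjusted p = 0.190). Glycolysis genes had 1 rise and 1 fall among 14, also adjusted over the list alone (camera adjusted p = 0.715), and p53 targets 2 rises among 18, also adjusted over the list alone (camera adjusted p = 0.401). Exhaustion and apoptosis genes had 2 rises among 14, with 2 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.765), while germline genes and CDK inhibitors had none past the threshold and 1 fall and 1 rise adjusted over the list alone (camera adjusted p = 0.401 and 0.932). Leaving out 1 array gave downward calls for epithelial markers (adjusted p = 9.44e-05 without germ-free Treg and 0.00744 without SPF Treg), IL-2 response genes (0.00062 and 0.00169 without the same arrays), imprinted genes (0.0357 and 0.0398 without the same arrays), Th2 genes (0.000489 without germ-free Treg and 0.0155 without SPF Non-Treg) and S phase genes (0.00174 without germ-free Non-Treg). Immediate early genes passed upward without germ-free Non-Treg (0.0144), SPF Non-Treg (0.0103) or either knockout array (0.0276 and 0.0335).

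Within subtypes, without a test, 368 genes were at least 2-fold higher and 1348 lower in germ-free Treg, and 976 higher and 634 lower in germ-free Non-Treg. The median of all genes was -0.27 and 0.44 in these arrays, and the Non-Treg split became 248 and 760 after quantile normalization, 58 and 1032 after trimmed mean scaling and 435 and 738 after 75th percentile scaling. In Treg these splits were 333 and 909, 536 and 982, and 693 and 815. Il1r1 and Ccl3 were at -6.16 and -5.13 in germ-free Non-Treg, and Nebl at -4.54 in germ-free Treg. The germ-free ratios of the subtypes correlated across genes at r = 0.45 (Spearman's rho 0.40), while 45.9% of genes had the same sign in both.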

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

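The tests of array scaling, of carried-over cells and of other mouse differences for the interferon genes, both tests of the B cell genes and the test of the Reg genes were chosen only after the result was seen.

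The knockout effect differed between Treg and Non-Treg cells for 5 genes by a test of the difference itself (111 at an unadjusted p under 0.05). Il10 had an interaction of -4.01 (limma adjusted p = 0.0181), with ratios of -2.81 within Treg and 1.21 within Non-Treg. Igk-V21 at 5.36, Igkv6-14 at 4.05, Klrd1 at 4.23 and Il1b at 4.10 ran the other way (limma adjusted p = 3.74e-05, 0.0428, 0.0245 and 0.0181). The knockout ratios of the B cell, CD8 T and NK, and myeloid lists had medians of 1.49, 1.86 and 1.49 within Treg. Within Non-Treg these medians were 0.05, 0.15 and 0.29. Whether carried-over cells account for these genes was not tested. Limma called 0 genes under each of the 3 other scalings (163, 93 and 77 at an unadjusted p under 0.05 after quantile, trimmed mean and 75th percentile scaling), and 0 without either SPF array (53 and 54 unadjusted) and 1 without either germ-free array.

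The germ-free effect differed between the subtypes for 138 genes (2238 at an unadjusted p under 0.05). The largest positive differences were in Prss2 at 3.58, Tm4sf1 at 3.42, Adamts4 at 3.39, Plvap at 3.28 and Clps at 3.25, among them pancreatic enzyme and endothelial genes. The largest negative ones were in Igkv15-103 at -4.38, Tarbp2 at -4.21, Serf1 at -3.96, Camk2a at -3.85 and the cyclin Ccnb2 at -3.40. The median of all genes was -0.67 in this term, and -0.11, -0.02 and -0.27 after quantile, trimmed mean and 75th percentile scaling, where limma called 0 genes (1042, 1125 and 1556 unadjusted). Removing either wild-type array gave 0 (2397 and 2416 unadjusted), knockout Non-Treg 6 and knockout Treg 4.

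The Treg effect differed between C57BL/6 and IQI mice for 136 genes (567 at an unadjusted p under 0.05), where strain and sort markers cannot be told apart. Igkv15-103 at 4.76, Srpk3 at 4.58, Ebf1 at 4.52, Ly6d at 4.44 and Igkv9-120 at 4.42 led in the C57BL/6 direction. Nxpe4 at -3.90, Esm1 at -3.27, Muc1 at -3.06, Cela2a at -2.99 and Cpa1 at -2.97 led in the IQI direction. The B cell list, which holds Ebf1, had median differences of 2.65 in wild type and 4.69 in the knockout. They were 0.32 in SPF and 0.99 in germ-free mice. Pancreatic enzyme genes had median signals of 0.14 to 0.27 in C57BL/6 arrays and of 8.48 to 153 in IQI arrays. Carried-over cells and sex were not separated from strain and sort in this term. The count went to 6 and 8 without knockout Non-Treg and Treg, to 59 and 56 without wild-type Non-Treg and Treg, and to 677 and 666 without SPF Non-Treg and Treg; quantile and trimmed mean scaling gave 0 (711 and 739 unadjusted).

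Probe sets that name no single gene stood outside the comparisons and carried signal too. Of 3354 above the filter, 411 passed between Treg and Non-Treg, 15 between knockout and wild type and 250 between germ-free and SPF. Of the 411, 286 were lower in Treg, against 209 of 911 named genes.

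Interferon genes were higher in both knockout arrays. Array scaling is argued against: a factor per array moves all but dim genes alike, whereas the list's median lay 1.88 above that of all genes as deposited, and quantile normalization, which also evens out the arrays' distributions, left it 2.20 above. B cells and other cells carried into knockout Treg alone are argued against as the source. The list's median ratio was 2.38 within Non-Treg, where the B cell list's was 0.05, and 1.38 within Treg. Other cells in knockout Non-Treg are not excluded. The median signal of B cell genes outside the fixed list was 3.16 in wild-type and 8.11 in knockout Non-Treg. That of CD8 T and NK markers was 4.93 and 13.4, although the median ratio of their tested genes was 0.15. A difference between the mice other than the genotype stays open: 7 of the 10 interferon genes that rose in the knockout also rose in germ-free mice, and 1 array per group cannot tell these apart. A role of the knockout itself stays open, as untested.

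B cell genes were higher in the C57BL/6 Treg arrays, although a gate on CD3 and CD4 would remove B cells. B cell RNA in the sort is consistent with 15 of 18 B cell genes outside the fixed list (83.3%), 0 of which another list holds, being at least 2-fold higher in Treg than in Non-Treg in both C57BL/6 conditions. A property of colonic Treg cells in general stays open: the list's median difference was 0.32 in SPF and 0.99 in germ-free mice, each from 1 pair of arrays, with 2.65 in wild type and 4.69 in the knockout. Cd79b and Ms4a1 had signals of 71.0 and 33.7 in wild-type and 102 and 94.7 in knockout Treg. How B cells or their RNA came through the gate was not tested.

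Reg and matrix genes fell in germ-free arrays. A general loss of carried-over epithelial cells is argued against for the Reg genes, whose median lay at least 3.56 below that of epithelial markers in each subtype (-3.63 and -4.20 against -0.03 and -0.64). Loss of a Reg-expressing part of these cells, or lower Reg expression in them, was not tested. Neither was pancreatic RNA. Pancreatic enzyme genes had medians of 85.2 in SPF and 153 in germ-free Treg, but 43.4 in SPF and 8.48 in germ-free Non-Treg. Fewer stromal cells may account for the matrix genes. Of 17 stromal genes outside the matrix with a probe set, 8 were above the filter and tested. Of these, 7 (87.5%) were at least 2-fold lower in the mean of both subtypes. The list's median signal was 0.281 to 0.477 in wild-type and knockout arrays. In Treg and Non-Treg it was 2.66 and 2.18 in SPF, and 1.10 and 0.857 in germ-free mice. A filter on the mean of all arrays therefore favors genes bright in SPF arrays, and the share may be too high. Col1a2, an abundant matrix gene, went from 41.0 and 51.4 to 3.57 and 3.91. Of 14 matrix genes, a list that shares 7 with the stromal markers, 13 passed, with a list median of -3.24. A gate on CD4 T cells would remove epithelial and stromal cells. The absence of microbes, which the design names, remained untested against a difference between the 2 pairs of arrays.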

How the results depend on the processing

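The trimmed mean and 75th percentile scalings, the pseudocount of 5, each gene's own variance and the Treg contrast within each strain were chosen only after the result was seen. Of the named genes past the threshold, 57 of 73 in the Treg contrast, 9 of 21 in the knockout contrast and 25 of 80 in the germ-free contrast passed under every scaling, and 55, 9 and 32 with each array left out. Of 34 list calls 28 held under every scaling, 19 with each array left out and 0 with an estimated correlation. Leaving out the same-median scaling, 68 counts stayed within 1.5 times, 73 were lower and 12 higher. In 6 of the 68 the more frequent direction turned over, as in germ-free Non-Treg, from 976 higher and 634 lower to 58 and 1032 after trimmed mean scaling. Over all alternatives, each call was counted once per setting in which it changed, so a call can count many times. In this count 1124 gene and 88 list calls were lost with their direction kept, and 160 and 43 were gained. Each gene's own variance gave 174 of the 1124, and the estimated correlation 34 of the 88. A further 7 gene and 4 list calls reversed direction. Scaling each array to the same median changed nothing, because the deposited columns already have it, and so tests nothing. With 10443 genes and 3 residual degrees of freedom, each gene's own variance left 2 genes for Treg, 0 for the knockout and 0 for the germ-free contrast (limma without moderation; 292 and 1243 at an unadjusted p under 0.05 for the last pair), and the fewer degrees of freedom are built into that setting. The same holds for camera with an estimated correlation, where 0 of 34 list calls held. Elsewhere the cause was not tested. Signal over background limits dim genes, and no background was used here. The condition term pairs the Treg and Non-Treg arrays of each condition, which the labels do not tie to the same mice, and a further pairing by replicate number could not be made, since each group holds 1 array.

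With the 10th percentile as pseudocount the knockout interaction called 10 genes, and with the 50th percentile the knockout and germ-free interactions called 3 and 82. Quantile normalization gave 44 genes for the knockout and 109 for the germ-free contrast, 0 for each of the 3 interactions (163, 1042 and 711 at an unadjusted p under 0.05 in limma), and 1008 at 2-fold in germ-free Non-Treg. Without a filter, Treg, knockout and both interactions gave 527, 33, 1 and 0 (2878 unadjusted for the last), over more genes tested. The 75th percentile filter, over fewer genes, gave 369, 28 and 492 for the contrasts, 2 and 22 for the knockout and strain interactions, and 110, 88, 847 and 889 within knockout Treg, knockout Non-Treg, germ-free Treg and germ-free Non-Treg. The mean of a gene's probe sets gave 603, 27 and 189, 0 for both interactions (73 and 1776 unadjusted), and 1130 and 936 within germ-free Treg and Non-Treg. Trimmed mean scaling gave 24 and 272 for knockout and germ-free contrasts and 0 for the 3 interactions (93, 1125 and 739 unadjusted). The 75th percentile scaling gave 32 for the knockout, 0 and 0 for its and the germ-free interaction (77 and 1556 unadjusted), and 33 for strain. A pseudocount of 5 gave interactions of 45, 1 and 243, and 168, 63, 563 and 748 within subtypes. Without a variance trend the germ-free contrast gave 471 and its interaction 0 (1685 unadjusted). For Treg, no condition term gave 14, strain as the only other term 413, and the 4 IQI arrays alone 201. The 4 C57BL/6 arrays alone gave 250 for the knockout and the 4 IQI arrays 443 for the germ-free contrast. At 1.5-fold the within-subtype counts were 1742, 912, 4107 and 4895, and at 3-fold 197, 83, 435 and 405.

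With each array left out, counts ran from 585 (without knockout Treg) to 1228 (without germ-free Treg) for Treg, from 35 (without knockout Treg) to 139 (without knockout Non-Treg) for the knockout, and from 356 (without SPF Non-Treg) to 1649 (without germ-free Treg) for the germ-free contrast; a lone remaining array was assumed to vary like the other groups. The knockout interaction, refitted without each of the 4 IQI arrays, ran from 0 to 1, the germ-free interaction, refitted without each of the 4 C57BL/6 arrays, from 0 to 6, and the strain interaction, without each of the 8 arrays, from 6 to 677 (for the 0 counts, limma left 53 and 54 genes unadjusted without either SPF array, and 2397 and 2416 without either wild-type array).

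Reversals under quantile normalization were in the germ-free contrast for Cd3e (-0.045), Trp53inp1 (-0.16), Pim1 (-0.30), Gapdh (-0.12), Mcl1 (-0.14) and Cd3d (-0.16), within germ-free Treg for Ctla4 (-0.11) and Cd3e (-0.016), and within germ-free Non-Treg for Cd3e (-0.073). With each array left out, the knockout median of effector Treg genes ran from -0.77 to 0.037 and that of B cell genes from -0.85 to 2.44, the reversed ends being those without knockout Treg. Ms4a1 in the germ-free contrast ran from -0.13 without SPF Treg to 3.30. The germ-free Treg signature list ran from -1.11 to -0.21, and the effector list from -0.94 to -0.19; without germ-free Non-Treg, at -0.21 and -0.32, both reversed relative to the other genes.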

Other observations

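Of the tests below, that of the germline genes was chosen only after the result was seen.

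Pancreatic digestive enzyme genes were present in the IQI arrays. Their median signal was 85.2 in SPF Treg, 43.4 in SPF Non-Treg, 153 in germ-free Treg and 8.48 in germ-free Non-Treg, against 0.14 to 0.27 in the C57BL/6 arrays. Genes of the sex chromosomes differed between the groups too, and were named after their values were seen. Xist had signals of 75.5 to 96.5 in C57BL/6, 59.4 to 60.6 in SPF and 1.14 to 1.30 in germ-free arrays. Eif2s3y, on the Y chromosome, had signals of at most 0.19 in C57BL/6, of 69.8 and 79.2 in SPF and of 144 and 149 in germ-free arrays. Both transcripts were thus present in the SPF arrays, Eif2s3y without bright Xist in germ-free arrays, and Xist without Eif2s3y in C57BL/6 arrays. By these transcripts the sex makeup of the cells differed between these sets of arrays. A difference in sex was not separated from strain and sort, or from the germ-free condition.

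The knockout and germ-free contrasts shared 10 genes that were higher in both, against 2.79 for independent lists: Cmpk2, Ifit1, Ifit3, Mx1, Oas2, Oasl1, Oasl2, Rsad2, Rtp4 and Usp18, of which several were named after their values were seen. The contrasts use different control arrays and share an error estimate. Another 10 genes were higher in the knockout and lower in germ-free mice, against 2.85, among them Ifng, Ccl5, Gzma and Col1a1.

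Loss of repression of silent genes in the knockout was asked in 2 ways. Outside the interferon list, 2 of 18179 genes, Clvs1 and Slfn4, went from a signal under 1 in both wild-type arrays to over 5 in both knockout arrays, and 0 went the other way, which is too few to decide. Slfn4 is itself known to be induced by interferon, although it was not in that list. Of 20 germline genes, dim ones included, 11 were higher in the knockout in both subtypes, 0 were lower in both and 3 were at least 2-fold higher in both, where 22.1% of all genes were higher in both. The hypothesis that germline genes may lose repression stays open, because the value lay between the bounds set for either outcome.

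Other splits of the arrays bear on the Treg contrast. With a condition term, 8 splits part each pair. The real one gave 911 genes and the highest other 0. The other splits turn the Treg and Non-Treg labels over in some conditions, so a real Treg difference enters their error. Low counts there are built in, and 8 splits are too few for a share under 0.05. This test therefore cannot decide about chance. Without a condition term, the real split gave 14 genes, and 2 of 35 splits, the real one included, gave as many; the highest other, which parted the strains, gave 4915, a structure of the samples larger than the Treg difference, so chance is not excluded there.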
